A study of Rattus norvegicus with 15 samples.

How the data were processed

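RNA was measured in dorsal CA1 of the hippocampus of male Sprague-Dawley rats aged 8 to 9 weeks, in 15 libraries that fall into 3 groups of 5: scrambled siRNA without training (replicates 1, 2, 9, 11 and 12), scrambled siRNA with contextual fear conditioning (5, 6, 10, 15 and 16) and Rnf20 siRNA with contextual fear conditioning (4, 8, 14, 18 and 20). Per the labels' protocols, the siRNA was of the Accell type, which enters cells without a transfection reagent, and was injected into dorsal CA1 5 days before training. RNA came from column purification of frozen tissue holding all brain cell types, and libraries were made with a stranded poly(A) kit and 14 cycles of PCR. The replicate numbers differ between the groups, so nothing pairs the samples. The labels number the libraries but do not state that each came from its own animal, so the p-values measure only the spread between these samples. The time between training and dissection is not in the labels.

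Per the submitters' processing notes, the authors trimmed reads with Trim Galore, inspected them with FastQC, counted them per gene with featureCounts 2.0.1 on the rat assembly Rnor_6.0 and normalised with DESeq2. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited table of raw values holds a read count for each of 22314 genes in each library, per the file headers. The deposited normalised signal table was checked against those counts: every value equalled the count over a DESeq2 median-ratio size factor, with 0 genes differing at a relative tolerance of 1e-06. The counts were used for every test, and the normalised table was not used further. Gene symbols are those of the deposited tables. The gene table supplied for names describes another rat assembly, so no coordinates, gene lengths or GC contents were used, and no check of length or GC bias was made.

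Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Of the 22314 genes, 399 had no count in any library, and 14880 passed edgeR's filterByExpr, which kept 99.9% of the counts. Libraries were scaled by TMM, and edgeR's quasi-likelihood F test with robust dispersions was fitted to all 15 libraries with 12 residual degrees of freedom, with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. The contrasts were trained against naive under scrambled siRNA, the label Rnf20 siRNA against scrambled siRNA in trained animals, trained Rnf20-labelled against naive scrambled siRNA libraries, and an F test among the 3 groups. No naive Rnf20 siRNA group is among the samples. Log2 fold changes carry standard errors from the quasi-likelihood fit. CPM values use the TMM-scaled library size and are given as mean ± SD with n = 5 per group. Principal components were taken from centred log2 CPM of the tested genes with a prior count of 2.

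Before the data were examined, 39 gene lists were fixed, 20 of pathways and complexes and 19 of cell type or region markers, together with the test, the contrasts, the threshold and the rule for named genes. Each list was tested with limma's camera on log2 CPM, with a preset inter-gene correlation of 0.01 and a minimum of 5 tested members, and again with a correlation estimated from the residuals and with fry, which asks whether a list's genes move, on balance, one way. Adjustment was over the 39 lists of a contrast. Lists share few members: the reactive glia list holds 3 microglia markers (Ctss, Trem2 and Tyrobp) and 1 astrocyte marker (Gfap), the glutamate list 2 CA3 markers, the presynaptic list 2 pan-neuronal markers, the channel list 1 CA3 marker, the cAMP list 1 striatal marker (Pde10a), the clock list 1 neocortical marker (Rorb) and the CA1 list 1 meningeal marker (Dcn). Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the edgeR p-values of a list's members only. The score of a list in a library is the mean log2 CPM of its tested members. Scores were compared by a two-sided exact permutation test over the 252 ways to divide 10 libraries into 5 and 5, whose smallest possible p is 0.00794, so that after adjustment over 39 lists none can pass unless at least 7 pass together; that test was added after the data were seen. The rule for named genes takes Rnf20, up to 12 higher and 12 lower genes by size of change among those past the threshold with a mean CPM of at least 1, then 2 to 4 members of smallest p past the threshold from each list, or, for a list without such members, its 1 or 2 members of smallest p given as values. Other genes are said to be chosen after their values were seen.

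Alternatives planned before the data were examined were DESeq2's Wald test, limma-voom with and without quality weights, median-ratio and upper-quartile scaling, no filter on low counts, a stricter filter of 1 CPM in 5 libraries, fitting only the 2 groups compared, 1 surrogate variable from sva, each library left out in turn, and the other list tests. Added after the data were seen were fits without the 4 libraries farthest out on component 1, without the 3 libraries with the lowest choroid plexus scores, and with the microglia score as a covariate. The fold changes of contrasts that share libraries were compared with simulated groups without change. The tests were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known amounts. Each gene was drawn independently, so no simulation here holds correlation between genes. The rates of recovery and of false calls may therefore differ in the real libraries. For the training contrast, edgeR called 44.8%, 77.6% and 86.4% of genes changed 1.5-fold, 2-fold and 4-fold among 14780 genes. For the trained groups the shares were 44.8%, 65.7% and 92.4% among 14762 genes, and for trained Rnf20-labelled against naive libraries 41.8%, 67.2% and 93.9% among 14777 genes. In these 3 simulations, false calls made up 2.11%, 4.26% and 3.57% of edgeR's calls, 4.73%, 2.82% and 4.35% of limma-voom's and 13.4%, 12.7% and 19.4% of DESeq2's, the last over 14880 genes. Regroupings of the samples were limited to 100 of the 126 possible for a pair of groups, with the real one included.

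Reads were counted without molecular identifiers, so intervals from read counts would cover counting error only, and all intervals given here come from the spread between libraries. Hemoglobin alpha copies, Hspa1a and Hspa1b, C4a and C4b, and ribosomal protein copies such as Rps4y2 and Rps18l1 have near-identical partners, so the division of reads among them is uncertain.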

Results

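Gene-level read counts described dorsal CA1 of rats that received scrambled or Rnf20 siRNA and were left naive or trained in contextual fear conditioning, a task in which an animal learns to associate a place with a shock. The 15 libraries formed 3 groups of 5: naive with scrambled siRNA (naive libraries below), trained with scrambled siRNA (scrambled trained libraries) and trained with the label Rnf20 siRNA (Rnf20-labelled libraries). Total counts ranged from 14249375 to 17046535 per library in the naive group, from 15342480 to 20644425 in the scrambled trained group and from 12537250 to 18458527 in the Rnf20-labelled group. Mitochondrially encoded transcripts took 8.47% to 13.3% of the counts, and the most abundant transcript, Mt-co1, took 2.48% to 3.83%. The biological coefficient of variation across replicates was 0.208.

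The libraries spread mainly along an axis with high levels of reactive glia genes at 1 end, and libraries of both trained groups lay far out on it. Component 1 held 35.7% of the variance, component 2 held 14.0% and component 3 held 12.3%. Scrambled trained replicates 10 and 15 lay at 53.5 and 41.0 on component 1 and Rnf20-labelled replicate 18 at 45.0, while Rnf20-labelled replicate 14 lay at -49.3. The reactive glia score, the mean log2 CPM of injury-responsive glial genes, was 5.81, 6.28 and 5.82 in the first 3 of these libraries and 2.99 in the last, against 4.11 to 4.74 in the naive libraries. Choroid plexus transcripts, which come from the secretory tissue of the ventricle next to the hippocampus, also varied: the score was 0.06 in scrambled trained replicate 5, 0.82 in scrambled trained replicate 16 and 1.43 in Rnf20-labelled replicate 20, and 3.82 to 6.31 in the other libraries. Striatal markers were highest in scrambled trained replicate 10, with a score of 5.85 against at most 4.85 elsewhere. The same library had the lowest CA1 marker score, 4.64 against at least 5.21 elsewhere.

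**Figure D1:**
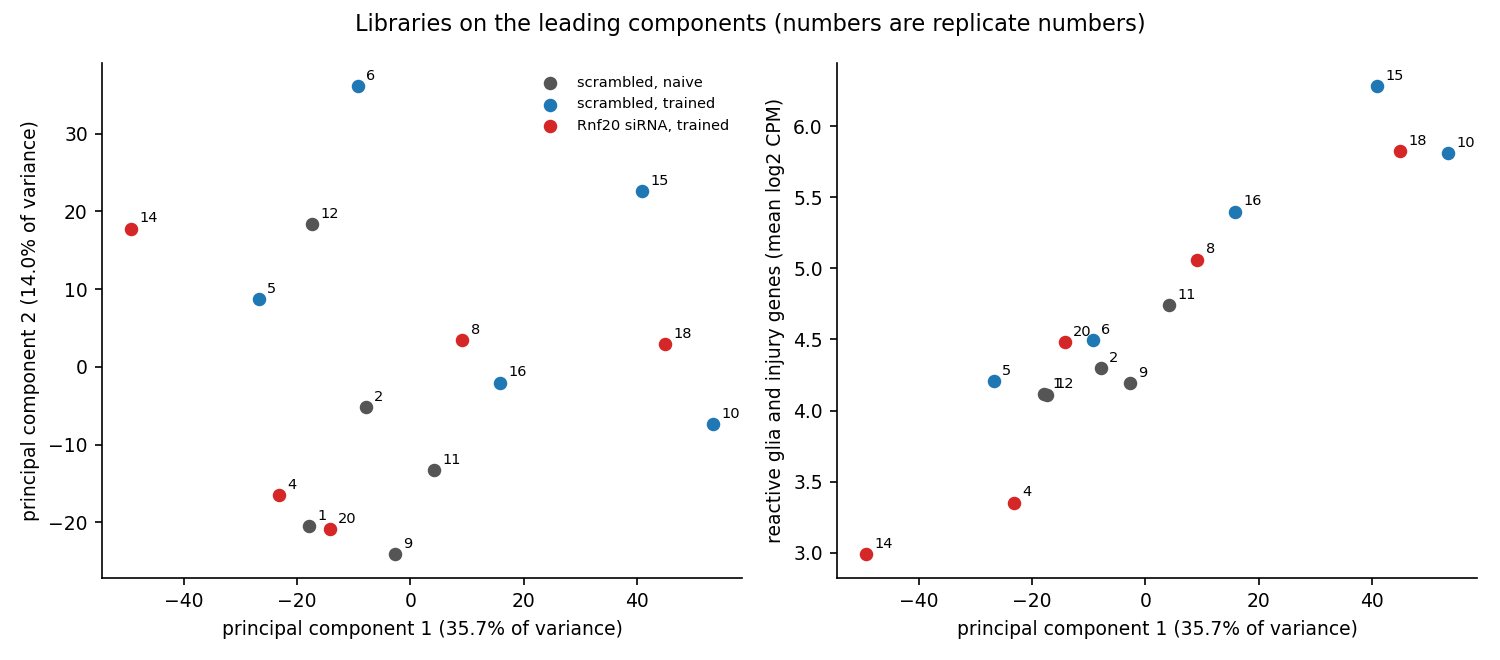
Position of each of the 15 libraries on components 1 and 2 of log2 CPM, and the reactive glia score of each library against component 1, with 1 point per library coloured by group. Scrambled trained replicates 10 and 15 and Rnf20-labelled replicate 18 lie far to the right, with scores of 5.81, 6.28 and 5.82.

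Rnf20 encodes a subunit of the ubiquitin ligase that monoubiquitinates histone H2B, and its level in each library checks the siRNA labels. Rnf20 was at 41.8 ± 2.28 CPM in naive libraries, 43.2 ± 5.39 CPM in scrambled trained libraries and 42.0 ± 2.32 CPM in trained libraries labelled Rnf20 siRNA (SD, n = 5 each). Its raw counts were 514 to 1011 per library. Between the trained groups the log2 fold change was -0.04 (SE 0.08; 95% interval -0.22 to 0.14; edgeR adjusted p = 0.945), which covers changes of -14.2% to 10.1%. The fold change was 0.05 (SE 0.08; adjusted p = 0.876) with training under scrambled siRNA and 0.01 (SE 0.08; adjusted p = 1.00) between trained Rnf20-labelled and naive libraries. The 5 libraries labelled Rnf20 siRNA held 38.3 to 44.6 CPM, inside the scrambled trained range of 36.4 to 48.5 CPM. Because the transcript was not lower under the label, the group is named by its label only (libraries labelled Rnf20 siRNA, or Rnf20-labelled), and no direction drawn from it is a direction of a measured loss of Rnf20 mRNA. Protein and H2B monoubiquitination were not analysed here.

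**Figure D2:**
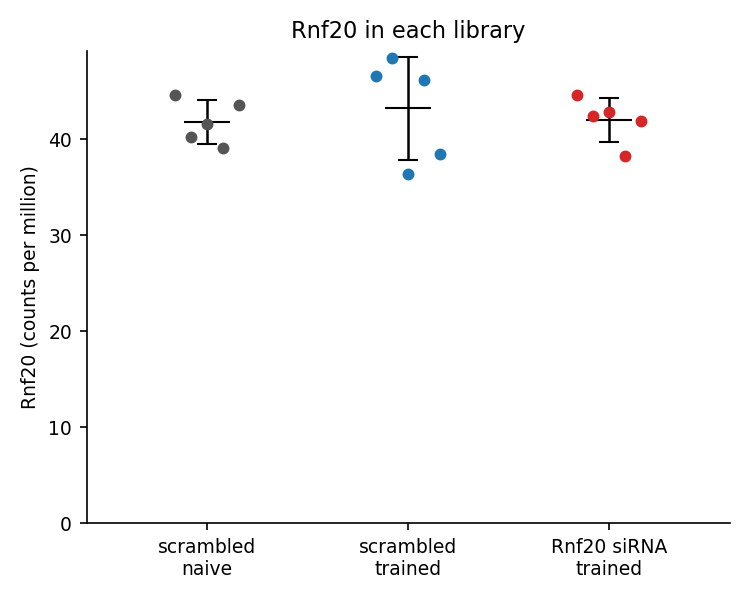
Rnf20 CPM in each library by group, with the group mean and SD (n = 5). The 3 group means lie at 41.8, 43.2 and 42.0 CPM and the groups overlap.

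Training under scrambled siRNA asks which transcripts differ in dorsal CA1 after contextual fear conditioning. Most genes that neurons and stressed cells switch on quickly were higher in scrambled trained than in naive libraries. Of 44 immediate early and activity-induced genes, 35 had a fold change above 0, with a median log2 fold change of 0.23. Junb, an AP-1 subunit, was at 43.9 ± 5.77 CPM after training and 26.7 ± 5.60 CPM in naive libraries (log2 fold change 0.72, SE 0.13; adjusted p = 0.00269 over the list alone and 0.379 over all genes), and every trained library exceeded every naive one. Egr2, a zinc finger transcription factor, was at 6.42 ± 1.26 against 1.88 ± 1.23 CPM (1.76, SE 0.42; adjusted p = 0.0156 over the list alone). These 2 members rose when adjusted over the list alone, and 0 did over all genes. Some well-known members, chosen after their values were seen, were not higher. Npas4 was at 4.06 ± 0.87 against 5.51 ± 2.68 CPM and Bdnf at 21.7 ± 6.51 against 24.7 ± 5.45 CPM. Arc, at 143 ± 41.8 against 103 ± 51.6 CPM, overlapped between the groups. Fos, chosen in the same way, had a higher mean after training, at 17.7 ± 4.45 against 9.38 ± 5.00 CPM, and overlapped as well. Of 19 glucocorticoid-responsive genes, 17 were above 0, with a median of 0.40, and 4 rose adjusted over the list alone. Among them were Per1, a clock component, at 55.3 ± 5.21 against 34.5 ± 8.63 CPM (0.68, SE 0.14; adjusted p = 0.00476 over the list alone), and Ddit4, an inhibitor of mTOR signalling, at 82.2 ± 9.39 against 60.6 ± 3.44 CPM (0.44, SE 0.10; adjusted p = 0.00639 over the list alone). Fkbp5, also chosen after its values were seen, was at 52.0 ± 8.60 against 50.1 ± 6.60 CPM. Sgk1, chosen likewise, had a higher mean, at 126.5 ± 46.6 against 77.2 ± 14.8 CPM, with overlap between the groups. All 24 heat shock and chaperone genes were above 0, with a median of 0.19, and 8 rose adjusted over the list alone, among them the co-chaperones Dnajb1 (63.6 ± 7.08 against 48.5 ± 4.96 CPM; 0.39, SE 0.09) and Bag3 (24.4 ± 4.43 against 17.9 ± 1.73 CPM; 0.45, SE 0.12).

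Camera placed these 3 lists higher with the preset correlation, at adjusted p = 9.58e-07 for immediate early genes, 1.11e-05 for glucocorticoid-responsive genes and 5.85e-09 for chaperones. The calls did not hold with an estimated correlation, at adjusted p = 0.249, 0.249 and 0.250. Their scores differed by the exact permutation test at p = 0.0159 each before adjustment and 0.103 after it, with 4.11 ± 0.08 against 3.79 ± 0.20 for immediate early genes and 4.42 ± 0.30 against 4.09 ± 0.06 for glucocorticoid-responsive genes. Single libraries moved several of these values by more than 1.5 times. The number of glucocorticoid-responsive genes past the list-alone threshold, 4 in the full set, was 2 without naive replicate 1, 8 without scrambled trained replicate 5 and 7 without replicate 6, and the median was 0.21 without scrambled trained replicate 15. The 8 chaperones became 4 without naive replicate 1 or 2, 1 without naive replicate 9, 0 without naive replicate 11, 2 without scrambled trained replicate 10, 1 without replicate 15 and 5 without replicate 16. The immediate early count of 2 was 6 by DESeq2 and 0 without the 3 libraries of lowest choroid plexus score. Without the 4 libraries far out on component 1, the glucocorticoid median was 0.16 and the chaperone median 0.11, with 2 members past the list-alone threshold in each list. The glucocorticoid median was also 0.21 with the microglia score as a covariate and with 1 surrogate variable.

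Subunits of the proteasome, the complex that degrades ubiquitinated proteins, and of the ribosome were slightly higher after training as whole groups. Of 34 proteasome genes (the list of the 26S complex), 32 were above 0 with a median log2 fold change of 0.13, 15 at an unadjusted p under 0.05. Psmb2, a core subunit, was at 77.1 ± 4.88 against 66.4 ± 2.32 CPM (0.22, SE 0.06; adjusted p = 0.0539 over the list alone), and Psmc4, an ATPase subunit, at 86.1 ± 4.24 against 75.8 ± 4.57 CPM (0.18, SE 0.06; adjusted p = 0.0539 over the list alone). By edgeR, 0 proteasome genes passed adjusted over the list alone, 5 did by DESeq2, and 12 did by edgeR without scrambled trained replicate 6. Camera gave adjusted p = 1.84e-11 with the preset correlation and adjusted p = 0.250 with an estimated correlation. The score was 6.47 ± 0.07 against 6.35 ± 0.04 (exact permutation p = 0.0159, adjusted p = 0.103). Of 71 cytosolic ribosomal protein genes, 70 were above 0, with a median of 0.19 (camera adjusted p = 4.27e-12; adjusted p = 0.586 with an estimated correlation) and 0 adjusted over the list alone. Rps9 was at 31.9 ± 7.40 against 21.6 ± 3.31 CPM. The exact permutation p of the ribosomal score was over 0.05 before adjustment. The ribosomal median was 0.03 with 1 surrogate variable and 0.06 with the microglia score as a covariate.

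Interferon-stimulated genes and injury-responsive glial genes were higher in most scrambled trained libraries, together with blood transcripts. Scrambled trained replicates 5 and 6 lay inside the naive range for the interferon score (2.54 and 3.58) and the reactive glia score (4.21 and 4.49). All 28 interferon-stimulated genes were above 0, with a median log2 fold change of 1.07, and 20 rose adjusted over the list alone. Irf9, a subunit of the transcription factor that interferon activates, was at 38.3 ± 8.29 against 23.4 ± 1.82 CPM (0.71, SE 0.15; adjusted p = 0.00726 over the list alone), and Isg15, a ubiquitin-like modifier, at 20.8 ± 12.7 against 6.28 ± 2.90 CPM (1.73, SE 0.49; adjusted p = 0.0400 over the list alone). Of 36 reactive glia and injury genes, 33 were above 0, with a median of 0.96, and 12 rose adjusted over the list alone, among them Timp1, a metalloproteinase inhibitor (37.3 ± 20.6 against 6.21 ± 1.70 CPM; 2.58, SE 0.59) and S1pr3, a sphingosine-1-phosphate receptor (54.5 ± 20.5 against 23.0 ± 4.57 CPM; 1.25, SE 0.38). Gfap, the intermediate filament of astrocytes, was at 5473 ± 1116 against 3220 ± 542 CPM (0.77, SE 0.24). All 5 blood cell genes rose adjusted over the list alone, with a median of 2.08; Hbb, the beta globin, was at 274 ± 173 against 68.3 ± 16.3 CPM and Hba-a2, an alpha globin, at 203 ± 161 against 41.5 ± 8.98 CPM. Leukocyte markers were above 0 in 8 of 8 (median 1.07) and microglia markers in 13 of 14 (median 0.46), with 0 adjusted over the list alone in both lists; Lyz2 had a fold change of 1.60, S100a9 of 2.59 and Itgam of 0.76.

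Camera gave adjusted p = 2.03e-14 for interferon-stimulated genes, 2.44e-10 for reactive glia, 1.50e-07 for blood, 0.000224 for leukocytes and 0.000463 for microglia. With an estimated correlation the values were adjusted p = 0.406, 0.580, 0.249, 0.406 and 0.586. Of the 39 lists, 7 had a score p under 0.05 by exact permutation before adjustment and 0 after it. The interferon and reactive glia lists were not among the 7. The list-alone count of 20 interferon-stimulated genes was 1 without naive replicate 1, 2 or 12, 9 without naive replicate 11, 2 without scrambled trained replicate 10, 1 without replicate 15 and 12 without replicate 16, and 1 by limma-voom. The count of 12 reactive glia genes was 0 without naive replicate 1, 2, 9 or 12 or scrambled trained replicate 10 or 15, 1 without naive replicate 11 and 20 without scrambled trained replicate 5, and 0 by limma-voom. The interferon median fell to 0.67 without scrambled trained replicate 15. Without the 4 libraries far out on component 1 the medians were 0.30 for interferon-stimulated genes, 0.58 for reactive glia, 0.19 for microglia and 0.56 for leukocytes, and 0 interferon-stimulated and 1 reactive glia gene passed adjusted over the list alone. With the microglia score as a covariate the medians of reactive glia and leukocytes were 0.25 and 0.22, that of interferon-stimulated genes was 0.77, and 1 interferon-stimulated and 3 reactive glia genes passed adjusted over the list alone. With 1 surrogate variable the 3 medians were 0.23, 0.37 and 0.60. Leukocytes were no longer called in either fit (camera adjusted p up to 0.0720). The blood score was 6.69 in scrambled trained replicate 6 and 3.55 in replicate 5, against 3.13 to 3.62 in the naive libraries.

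Synaptic and neuronal transcripts were lower by small amounts in scrambled trained libraries, and these differences followed the libraries on component 1. Presynaptic release genes were below 0 in 31 of 34 (median log2 fold change -0.22), voltage-gated channels in 40 of 42 (-0.18), glutamate receptors and postsynaptic density genes in 40 of 47 (-0.12), GABA receptor genes in 18 of 19 (-0.13), adhesion molecules encoded by long genes in 22 of 25 (-0.15) and pan-neuronal markers in 12 of 12 (-0.21). Rims1, a scaffold of the presynaptic active zone, was at 253 ± 48.9 against 334 ± 40.8 CPM (-0.40, SE 0.12), Kcna1 and Kcnq5, potassium channel subunits, had fold changes of -0.38 each, and the kainate receptor subunit Grik1 was at 6.99 ± 1.87 against 10.6 ± 0.82 CPM (-0.60, SE 0.19). In these 6 lists 0 genes passed adjusted over the list alone. Camera gave adjusted p = 8.13e-07, 6.83e-06, 0.000274, 0.0167, 0.00142 and 0.00126 in the order named. With an estimated correlation these were adjusted p = 0.580, 0.586, 0.703, 0.743, 0.703 and 0.586. The 6 medians were, without the 4 libraries far out on component 1, -0.08, -0.05, 0.07, 0.00, 0.01 and -0.04, and 0 of the 6 lists were called. With the microglia score as a covariate the medians were -0.08, -0.04, 0.01, 0.00, -0.04 and -0.03, and the presynaptic list alone was called. With 1 surrogate variable they were -0.05, -0.02, 0.08, 0.03, 0.01 and 0.00, with 0 called.

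Single scrambled trained libraries moved the neuronal values as well. Without replicate 10 the medians were -0.15 for presynaptic, -0.02 for glutamate (adjusted p = 0.115), -0.03 for GABA, -0.09 for long adhesion genes and -0.13 for pan-neuronal markers. Without replicate 15 they were -0.07 for glutamate and for GABA genes, and without replicate 16 -0.08 for GABA genes. Without replicate 5 they were -0.18 for glutamate, -0.22 for GABA and -0.31 for pan-neuronal genes, and without replicate 6 -0.19 for glutamate, -0.21 for GABA and -0.29 for channel genes. Without naive replicate 12 the glutamate median was -0.07. The GABA receptor call was lost without naive replicate 1 or scrambled trained replicate 10, 15 or 16 (adjusted p up to 0.220), and the long adhesion gene call without scrambled trained replicate 16 (adjusted p = 0.0768).

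Among cell type markers, those of CA3 neurons, oligodendrocytes, endothelial cells and choroid plexus were lower in scrambled trained libraries. CA3 markers were below 0 in 11 of 11 (median -0.29; camera adjusted p = 5.52e-05; adjusted p = 0.304 with an estimated correlation), and the proteoglycan gene Spock1 fell adjusted over the list alone, from 115 ± 16.0 to 78.9 ± 8.93 CPM (-0.54, SE 0.14; adjusted p = 0.0146 over the list alone). Oligodendrocyte markers were below 0 in 14 of 15 (median -0.25; camera adjusted p = 6.83e-06; adjusted p = 0.580 with an estimated correlation). The 3 that fell adjusted over the list alone include the myelin protein gene Opalin (198 ± 52.1 against 324 ± 55.5 CPM; -0.71, SE 0.17) and the connexin gene Gjc3 (19.7 ± 5.02 against 29.2 ± 2.83 CPM; -0.57, SE 0.16). Endothelial markers were below 0 in 10 of 11 (median -0.16; camera adjusted p = 0.0462; adjusted p = 0.729 with an estimated correlation), and Kdr, a VEGF receptor, fell adjusted over the list alone (12.0 ± 1.14 against 15.9 ± 1.15 CPM; -0.41, SE 0.11). Choroid plexus markers were below 0 in 14 of 14 (median -0.85; camera adjusted p = 9.58e-07; adjusted p = 0.580 with an estimated correlation), with 0 adjusted over the list alone; Enpp2 was at 387 ± 299 against 638 ± 250 CPM.

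These marker values depended on single libraries. The list-alone counts of CA3 (1), oligodendrocyte (3) and endothelial (1) markers were 0, 1 and 1 without naive replicate 9; 3, 3 and 0 without naive replicate 11; 2, 1 and 1 without scrambled trained replicate 5; 2, 7 and 1 without replicate 10; and 0, 1 and 0 without replicate 16. The oligodendrocyte count was 0 without scrambled trained replicate 6, and the endothelial count was 0 without naive replicate 1 or 12 or scrambled trained replicate 6 or 15. The oligodendrocyte median was -0.13 without scrambled trained replicate 6 and -0.42 without replicate 10. The CA3 median was -0.17 with 1 surrogate variable and -0.18 with the microglia covariate, and the oligodendrocyte median was -0.50 with 1 surrogate variable and -0.16 without the 3 libraries of lowest choroid plexus score. The endothelial median was -0.07 without naive replicate 11 or scrambled trained replicate 10, and its call was lost without naive replicate 1, 2 or 11 or scrambled trained replicate 10 or 15 (adjusted p up to 0.276), without a filter on low counts (adjusted p = 0.121), with 1 surrogate variable (-0.06; adjusted p = 0.336) and with the microglia covariate (-0.08; adjusted p = 0.180). That median was -0.30 without the 3 libraries of lowest choroid plexus score. The choroid plexus median was -0.55 without scrambled trained replicate 5, -1.75 without replicate 10, -2.33 by limma-voom, -1.81 with 1 surrogate variable, -1.29 with the microglia covariate and -0.21 without the 3 libraries of lowest choroid plexus score (camera adjusted p = 0.503). The oligodendrocyte median was, without the 4 libraries far out on component 1, -0.52 and 12 members passed adjusted over the list alone, the endothelial median was 0.02 (camera adjusted p = 0.803) and the choroid plexus median -2.52.

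The remaining lists did not pass camera for training with all libraries. Among chromatin genes, the median fold change was 0.02 for the H2B ubiquitination machinery (camera adjusted p = 0.861), 0.01 for H3K4 and H3K79 methylation enzymes (0.861) and -0.01 for other chromatin and DNA methylation enzymes (0.659); the largest differences by p were Usp49 (-0.28) and Atxn7l3 (-0.20), Setd1a (-0.12) and Dpy30 (0.15), and Hdac1 (0.25) and Dnmt1 (0.21). Medians were -0.06 for cAMP, CREB and MAPK signalling (0.107), 0.01 for cholesterol synthesis (0.684), 0.03 for nuclear-encoded oxidative phosphorylation (0.117), -0.08 for mitochondrially encoded genes (0.234) and -0.09 for core clock genes (0.296). Among marker lists they were 0.05 for CA1 neurons (0.891), 0.18 for dentate granule neurons (0.273), -0.09 for GABAergic interneurons (0.638), -0.06 for astrocytes (0.436), -0.06 for oligodendrocyte precursors (0.508), -0.19 for pericytes (0.234), -0.19 for ependymal cells (0.369), -0.01 for meningeal fibroblasts (0.296), -0.22 for thalamus (0.296), -0.16 for neocortex (0.234) and 0.22 for striatum (0.211). In the pericyte list, Tagln was higher (124 ± 96.7 against 34.2 ± 4.95 CPM; 1.85) and Rgs5 lower (39.2 ± 3.38 against 50.2 ± 3.28 CPM; -0.35) adjusted over the list alone, with 3 members passing; none passed without naive replicate 1 or 11 or scrambled trained replicate 10, and 1 without scrambled trained replicate 15. The list median, mean and camera direction differed in sign for 7 training lists, none of them called: H2B ubiquitination, H3K4 and H3K79 enzymes, cholesterol synthesis, CA1 neurons, interneurons, pericytes and striatum.

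Several of these lists were called when libraries were left out. Oxidative phosphorylation genes were called higher without naive replicate 9 or scrambled trained replicate 6, 10 or 15 (adjusted p from 6.36e-05 to 0.0401). They were also called higher without the 4 libraries far out on component 1 (2.28e-05), with the microglia covariate (0.000340) and with 1 surrogate variable (0.0209), and called lower without the 3 libraries of lowest choroid plexus score (0.00222). The cAMP signalling list was called lower without naive replicate 2 or scrambled trained replicate 5 or 6 (adjusted p down to 0.00841). Without scrambled trained replicate 10, striatum (1.29e-08), thalamus, meningeal, pericyte and ependymal markers were called lower and dentate markers higher. Without naive replicate 12, striatum, neocortex and pericyte markers were called lower. Without scrambled trained replicate 16, mitochondrially encoded genes were called lower (0.0433). Markers of oligodendrocyte precursors and of ependymal cells were called lower with 1 surrogate variable, with the microglia covariate and without the 4 libraries (adjusted p up to 0.00600). Without those 4, CA1 markers were called higher (0.000951) and striatum, thalamus and meningeal markers lower. With 1 surrogate variable dentate markers and the H2B ubiquitination machinery (0.0477) were also called higher and striatum lower. Without the 3 libraries of lowest choroid plexus score mitochondrially encoded genes, astrocyte and neocortex markers were called lower.

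Over all 14880 genes, edgeR called 0 genes for training (smallest adjusted p = 0.379), with 1484 genes at an unadjusted p under 0.05 (985 higher, 499 lower) where chance gives 744. Limma-voom called 0 and DESeq2 called 53 (39 higher, 14 lower). Tubb2b, a beta tubulin chosen after its values were seen, had the smallest DESeq2 adjusted p (0.000217, log2 fold change 0.50), and Junb was also among the 53. With 1 surrogate variable edgeR called 1 gene, Timp1. Of the 39 lists, camera called 20 (10 higher, 10 lower) with the preset correlation and 0 with an estimated correlation, and fry called 0.

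**Figure D3:**
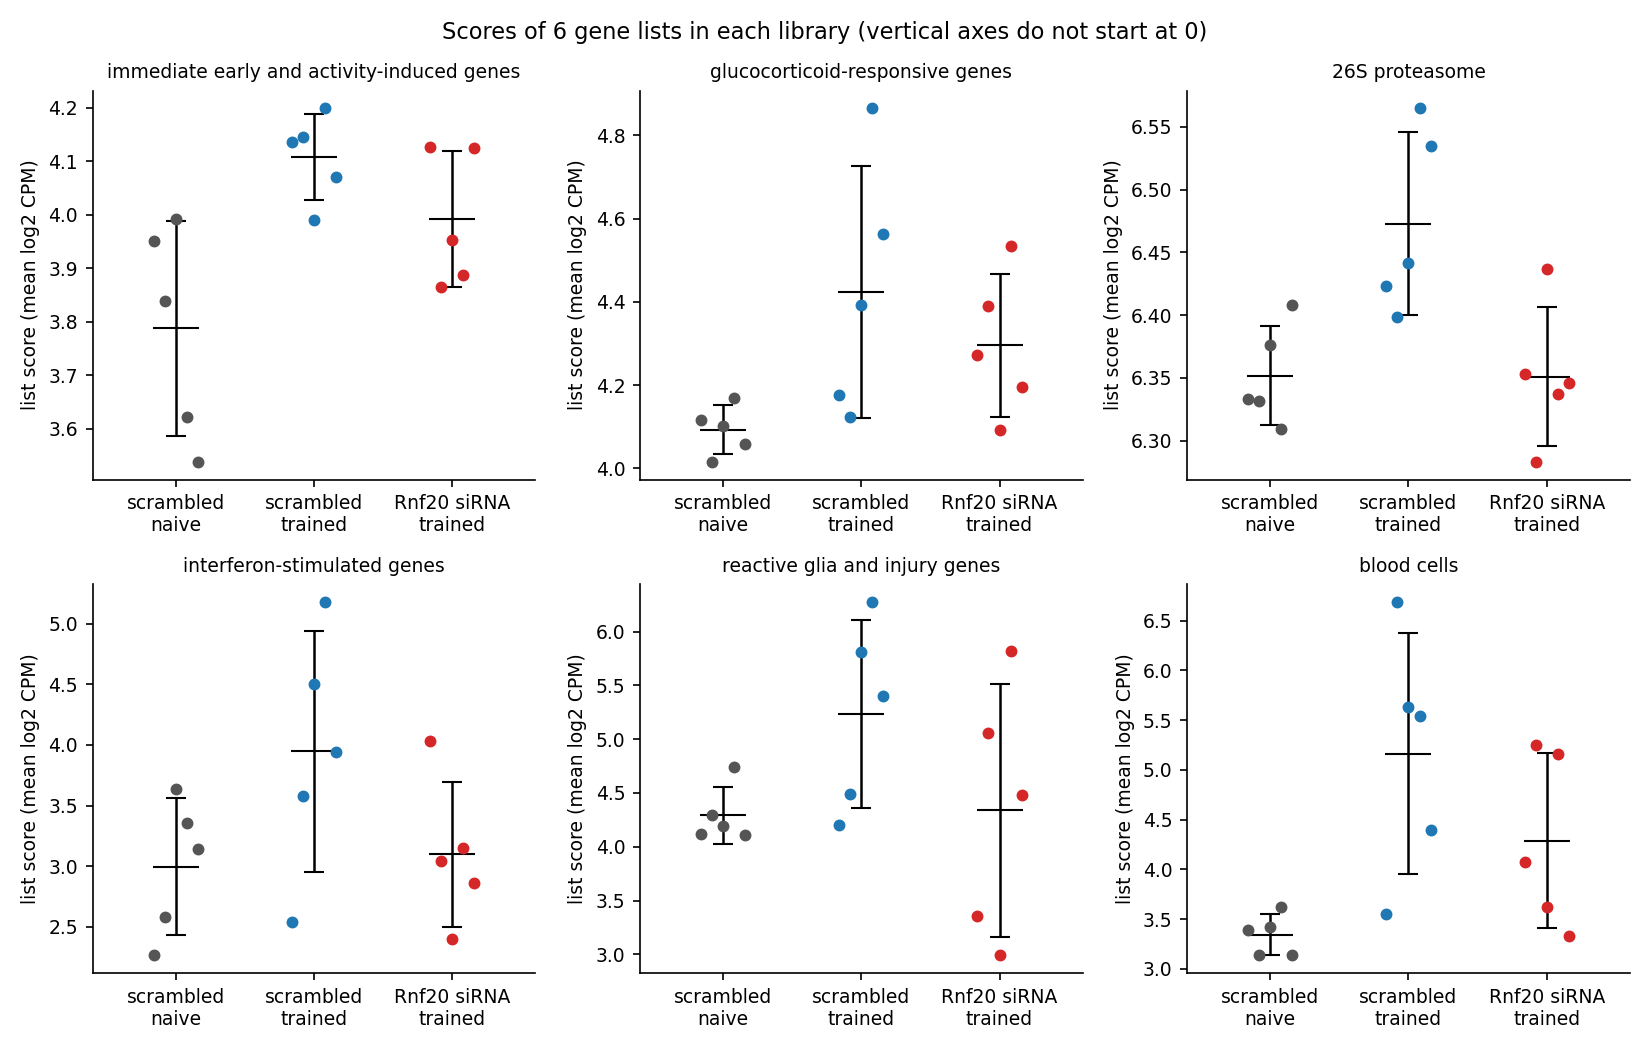
Score (mean log2 CPM of tested members) of selected gene lists in each of the 15 libraries by group, with group means and SD (n = 5). The proteasome score averages 6.47 in scrambled trained and 6.35 in naive libraries, and the blood score spreads from 3.55 to 6.69 in scrambled trained libraries.

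The comparison of the trained groups asks which transcripts differ between trained animals with the Rnf20 and the scrambled siRNA label. In libraries labelled Rnf20 siRNA, proteasome genes were lower and genes of synapses, channels and H3K4 methylation higher than in scrambled trained libraries. Of 34 proteasome genes, 32 were below 0, with a median log2 fold change of -0.13, 12 at an unadjusted p under 0.05. Psmc4 had a log2 fold change of -0.20 (SE 0.06) from 86.1 ± 4.24 CPM in scrambled trained libraries, and Psmc3, another ATPase subunit, was at 118 ± 5.63 against 135 ± 5.24 CPM (-0.20, SE 0.06), and in both genes every library labelled Rnf20 siRNA was below every scrambled trained library (adjusted p = 0.0912 over the list alone). Camera gave adjusted p = 2.48e-13 and adjusted p = 0.498 with an estimated correlation, and the score was 6.35 ± 0.06 against 6.47 ± 0.07 (exact permutation p = 0.0238, adjusted p = 0.619). In this comparison 2 of the 39 lists had a score p under 0.05 by exact permutation before adjustment. That is about the number that chance gives at 5%, and 0 passed after adjustment. By edgeR, 0 proteasome genes passed adjusted over the list alone, and 6 did without Rnf20-labelled replicate 14. Of 16 H3K4 and H3K79 methylation enzymes, 11 were above 0 (median 0.12; camera adjusted p = 0.00871; adjusted p = 0.498 with an estimated correlation). Kmt2d and Kmt2a, H3K4 methyltransferases, rose adjusted over the list alone (adjusted p = 0.0311 each), Kmt2d at 222 ± 25.7 against 183 ± 11.4 CPM (0.28, SE 0.08) and Kmt2a at 122 ± 15.4 against 91.2 ± 17.9 CPM (0.42, SE 0.13). That count of 2 became 0 without scrambled trained replicate 5, 15 or 16 or Rnf20-labelled replicate 4, 18 or 20. The camera call was lost without scrambled trained replicate 16 or Rnf20-labelled replicate 18 (adjusted p up to 0.0820), and the median was 0.06 without scrambled trained replicate 16. Without the 3 libraries of lowest choroid plexus score the median was 0.04 (camera adjusted p = 0.353), with 0 members past the list-alone threshold.

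Lists of synaptic, channel and signalling genes, clock genes, and neuronal and oligodendrocyte markers were higher as groups, with small median changes. Voltage-gated channels were above 0 in 41 of 42 (median 0.22; camera adjusted p = 3.96e-08), presynaptic genes in 32 of 34 (0.19; 3.13e-07), glutamate receptor genes in 42 of 47 (0.14; 3.49e-06), long adhesion genes in 24 of 25 (0.12; 0.000150), cAMP, CREB and MAPK signalling in 37 of 44 (0.10; 0.00222), GABA receptor genes in 17 of 19 (0.10; 0.0277), core clock genes in 13 of 18 (0.12; 0.0164), pan-neuronal markers in 12 of 12 (0.17; 0.00904), CA3 markers in 10 of 11 (0.17; 0.00222) and oligodendrocyte markers in 13 of 15 (0.10; 0.0143). In these 10 lists 0 genes passed adjusted over the list alone, and none of the calls held with an estimated correlation (adjusted p = 0.498 for channels, presynaptic genes and CA3 markers, 0.499 for cAMP signalling, 0.542 for glutamate and clock genes, 0.569 for long adhesion genes, 0.640 for pan-neuronal markers and 0.834 for GABA and oligodendrocyte genes). Rims1 was at 335 ± 22.5 against 253 ± 48.9 CPM (0.41, SE 0.12), its relative Rims2 had a fold change of 0.41, and the channel genes Kcnd3 and Cacna1d of 0.34 and 0.30. Without the 4 libraries far out on component 1 the medians were 0.07 for channels, 0.11 for presynaptic genes, -0.02 for glutamate genes, 0.07 for long adhesion genes, 0.04 for cAMP signalling, -0.03 for GABA genes, -0.01 for pan-neuronal markers, 0.07 for CA3 markers and 0.42 for oligodendrocyte markers. Of the 10 lists those of presynaptic, long adhesion and oligodendrocyte genes were still called. With the microglia score as a covariate the medians were 0.02 for channels and cAMP signalling, 0.00 for presynaptic and clock genes, -0.01 for glutamate, -0.04 for long adhesion, -0.05 for GABA and -0.09 for pan-neuronal genes and 0.11 for CA3 markers. The oligodendrocyte list alone was still called. With 1 surrogate variable the same list alone was called, and the medians of GABA (-0.05), long adhesion (-0.03) and pan-neuronal genes (-0.07) were below 0. The oligodendrocyte median was 0.31 with 1 surrogate variable. Limma-voom with quality weights gave 0.16 for GABA, 0.19 for long adhesion and 0.18 for oligodendrocyte genes. Without the 3 libraries of lowest choroid plexus score the oligodendrocyte median was -0.02 (camera adjusted p = 0.388), the GABA median 0.19 and the pan-neuronal median 0.26.

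Leaving out 1 library ended several of these calls. Without Rnf20-labelled replicate 14 the calls for GABA genes, cAMP signalling, CA3 (adjusted p = 0.147) and pan-neuronal markers were lost, and the medians were 0.06 for glutamate and CA3 genes, 0.02 for GABA genes, 0.07 for pan-neuronal markers, 0.12 for presynaptic genes and 0.06 for cAMP signalling. Without Rnf20-labelled replicate 18 the medians were 0.29 for presynaptic, 0.22 for glutamate, 0.23 for long adhesion, 0.21 for GABA, 0.28 for pan-neuronal, 0.26 for CA3, 0.15 for cAMP and 0.04 for oligodendrocyte genes, the last no longer called. Without Rnf20-labelled replicate 20 the presynaptic median was 0.12, the CA3 median 0.25 and the clock median 0.07, with the clock call lost, and without replicate 4 the GABA call and the oligodendrocyte call (median 0.04) were lost. Without scrambled trained replicate 10 the GABA (0.05), pan-neuronal (0.08) and clock calls were lost, the glutamate median was 0.08, the CA3 median 0.28 and the oligodendrocyte median 0.26. Without replicate 15 the GABA, clock and pan-neuronal (0.09) calls were lost, and without replicate 16 the GABA call was lost and the medians were 0.15 for channels, 0.07 for long adhesion and 0.05 for cAMP genes. Without replicate 5 the medians were 0.28 for CA3, 0.18 for GABA and 0.23 for long adhesion genes, and without replicate 6 they were 0.26, 0.19 and 0.24, with 0.25 for glutamate genes. The oligodendrocyte call was lost without either (medians 0.02 and 0.00; adjusted p up to 0.550), and its median was 0.18 without Rnf20-labelled replicate 14. Across these fits the lost calls had adjusted p up to 0.551 for GABA, 0.0710 for cAMP, 0.118 for clock and 0.196 for pan-neuronal genes.

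Interferon, reactive glia and blood transcripts were lower on average in libraries labelled Rnf20 siRNA than in scrambled trained libraries, but the groups overlapped. The interferon score ran from 2.40 to 4.03 in Rnf20-labelled and from 2.54 to 5.18 in scrambled trained libraries. For reactive glia the ranges were 2.99 to 5.82 and 4.21 to 6.28, and for blood 3.33 to 5.25 and 3.55 to 6.69. None of these scores had an exact permutation p under 0.05 before adjustment. Interferon-stimulated genes were below 0 in 28 of 28 (median log2 fold change -0.94; camera adjusted p = 2.48e-13), reactive glia genes in 35 of 36 (-0.65; 2.41e-12), chaperones in 23 of 24 (-0.14; 5.95e-06), microglia markers in 13 of 14 (-0.40; 5.95e-06), leukocyte markers in 7 of 8 (-0.43; 0.00115), blood genes in 5 of 5 (-1.0; 0.00288) and ribosomal protein genes in 64 of 71 (-0.09; 0.000546). With an estimated correlation the values were adjusted p = 0.498 for the first 6 lists and 0.881 for ribosomal proteins. Irf9 was at 26.7 ± 5.22 against 38.3 ± 8.29 CPM (-0.52, SE 0.15), Cxcl10, a chemokine, at 2.05 ± 0.84 against 8.58 ± 9.91 CPM (-2.06, SE 0.67), Lcn2, an iron-binding acute phase protein, at 5.49 ± 3.62 against 49.8 ± 59.8 CPM (-3.18, SE 0.92) and Gfap at 3609 ± 1507 against 5473 ± 1116 CPM (-0.60, SE 0.24). Adjusted over the list alone 0 of these genes passed in the full set, 28 interferon-stimulated and 5 blood genes did without scrambled trained replicate 5, and 19 reactive glia genes did without Rnf20-labelled replicate 18. Without scrambled trained replicate 15 the medians were -0.44 for interferon, -0.39 for reactive glia and -0.08 for chaperones. Without replicate 6 the blood median was -0.55 (adjusted p = 0.103) and the ribosomal median -0.16, and the ribosomal call was lost without scrambled trained replicate 10 or 16 or Rnf20-labelled replicate 14 (adjusted p up to 0.361; medians -0.02, -0.03 and -0.02), with a median of -0.05 without Rnf20-labelled replicate 4. Without Rnf20-labelled replicate 18 the medians were -1.30 for reactive glia, -0.65 for microglia, -0.67 for leukocytes and -0.22 for ribosomal proteins, and without replicate 8 -0.76 for leukocytes. The leukocyte median was -0.72 without a filter on low counts, -0.71 by DESeq2, -0.95 by limma-voom and -1.18 with its quality weights, which gave -1.17 for reactive glia. Without the 4 libraries far out on component 1, 2 of them in each group, the median was 0.01 for interferon (camera adjusted p = 0.828), -0.36 for reactive glia and -0.11 for leukocytes (camera adjusted p = 0.0630), and blood was no longer called (camera adjusted p = 0.103). With the microglia score as a covariate the medians were -0.56 for interferon, -0.17 for reactive glia (camera adjusted p = 0.228), -0.64 for blood (camera adjusted p = 0.207) and 0.04 for leukocytes (camera adjusted p = 0.686). With 1 surrogate variable they were -0.42 for interferon, -0.18 for reactive glia and -0.09 for leukocytes (camera adjusted p = 0.179). Without the 3 libraries of lowest choroid plexus score, 24 interferon-stimulated and 5 blood genes passed adjusted over the list alone. The ribosomal direction turned to higher with 1 surrogate variable (adjusted p = 0.00642) and with the microglia covariate (adjusted p = 0.00847).

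The H2B ubiquitination machinery did not pass (median -0.01; camera adjusted p = 0.677), with Ssrp1, a subunit of the histone chaperone FACT, at -0.15 and Atxn7l3 at 0.22. Other chromatin genes had a median of 0.04 (0.0626), with Kdm6b, an H3K27 demethylase, at 0.24 and Tet2 at 0.27. Immediate early genes had a median of -0.09 (0.111) and glucocorticoid-responsive genes of -0.06 (0.447). The immediate early list was called lower without scrambled trained replicate 10 or Rnf20-labelled replicate 4 or 20 (adjusted p = 0.0103, 0.0226 and 0.0202), with 1 surrogate variable (0.00704) and with the microglia covariate (0.000234). Its median was -0.01 without Rnf20-labelled replicate 18, -0.04 without replicate 8 and -0.05 without scrambled trained replicate 6. The glucocorticoid median was -0.13 without scrambled trained replicate 10, -0.11 without replicate 16, -0.04 without replicate 15 and -0.01 without Rnf20-labelled replicate 20. The H2B ubiquitination machinery was called lower with 1 surrogate variable (0.0231) and with the microglia covariate (0.0209), and other chromatin genes higher without scrambled trained replicate 6 or 15 or Rnf20-labelled replicate 20 (adjusted p down to 0.0104). Leaving out 1 library gave calls to other lists not called with all libraries. Oxidative phosphorylation was called (lower without scrambled trained replicate 6 or 15 or Rnf20-labelled replicate 20, higher without scrambled trained replicate 16), as were mitochondrially encoded genes (higher without scrambled trained replicate 5 or 16 or Rnf20-labelled replicate 20). So were choroid plexus markers (higher without scrambled trained replicate 10 or 15 or Rnf20-labelled replicate 20), astrocyte markers (higher without scrambled trained replicate 5 or Rnf20-labelled replicate 20) and ependymal markers (lower without scrambled trained replicate 5). Without scrambled trained replicate 10, CA1 markers were called lower and striatum markers higher (7.85e-09). The median, mean and camera direction differed in sign for 6 lists, none of them called: H2B ubiquitination, cholesterol synthesis, interneurons, pericytes, choroid plexus and striatum. Over all 14880 genes, edgeR called 0 (smallest adjusted p = 0.832), with 835 at an unadjusted p under 0.05 (392 higher, 443 lower) where chance gives 744. Limma-voom called 0 and DESeq2 called 1, Pkd1, which encodes polycystin 1 and was named after its values were seen (0.39; adjusted p = 0.0124). Camera called 19 of 39 lists (11 higher, 8 lower), 11 with the microglia covariate and 0 with an estimated correlation, and fry called 0.

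The comparison of trained libraries labelled Rnf20 siRNA with naive libraries asks which training differences are also seen under that label. Glucocorticoid-responsive and immediate early genes were higher here too, and proteasome genes were not. Of 19 glucocorticoid-responsive genes, 17 were above 0 (median log2 fold change 0.20; camera adjusted p = 7.77e-07; adjusted p = 0.115 with an estimated correlation; exact permutation p = 0.0397, adjusted p = 0.464). Per1 rose adjusted over the list alone, from 34.5 ± 8.63 to 58.8 ± 8.21 CPM (0.77, SE 0.14; adjusted p = 0.00145 over the list alone), as did Ddit4, from 60.6 ± 3.44 to 79.5 ± 12.6 CPM (0.39, SE 0.10; adjusted p = 0.0168 over the list alone). Of 44 immediate early genes, 35 were above 0 (median 0.17; camera adjusted p = 1.40e-06; adjusted p = 0.333 with an estimated correlation), and Junb (37.8 ± 2.68 against 26.7 ± 5.60 CPM; 0.50, SE 0.13) and Egr2 (5.51 ± 2.83 against 1.88 ± 1.23 CPM; 1.54, SE 0.42) rose adjusted over the list alone (adjusted p = 0.0459 each). The exact permutation p of the immediate early score was over 0.05 before adjustment. Proteasome genes were above 0 in 17 of 34 (camera adjusted p = 0.854). Of 16 H3K4 and H3K79 enzymes, 11 were above 0 (median 0.06; camera adjusted p = 0.00256; adjusted p = 0.522 with an estimated correlation), and Kmt2a (122 ± 15.4 against 89.0 ± 5.71 CPM; 0.46, SE 0.13) and Kmt2d (222 ± 25.7 against 185 ± 7.21 CPM; 0.27, SE 0.08) rose adjusted over the list alone. Their rises between the trained groups came from the same Rnf20-labelled libraries and are not independent of these. The score of other chromatin genes, with a median fold change of 0.05 (camera adjusted p = 0.104), differed at the exact permutation p = 0.00794 before adjustment, the smallest that these permutations can give, and at adjusted p = 0.310 after it.

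Single libraries changed these counts of 2. For immediate early genes 0 passed without naive replicate 1, 11 or 12 or Rnf20-labelled replicate 4, 8, 14 or 20, and 0 without the 4 libraries far out on component 1. For glucocorticoid-responsive genes 1 passed without naive replicate 1 or Rnf20-labelled replicate 8, and 4 without naive replicate 12 or Rnf20-labelled replicate 20. For H3K4 and H3K79 enzymes 0 passed without naive replicate 1 or 11 or Rnf20-labelled replicate 8 or 20, and 1 without naive replicate 9 or 12 or Rnf20-labelled replicate 18; the median was 0.03 without the last and with 1 surrogate variable, and 0.01 by limma-voom with quality weights.

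Other lists called in this comparison had small medians or belonged to blood and marker lists. Ribosomal proteins were above 0 in 69 of 71 (median 0.11; camera adjusted p = 4.23e-07), chaperones in 18 of 24 (0.05; 0.0133), blood genes in 5 of 5 (1.09; 3.97e-05) and dentate granule markers in 11 of 13 (0.20; 0.0331). Choroid plexus markers were below 0 in 14 of 14 (-1.16; 7.68e-07), oligodendrocyte markers in 14 of 15 (-0.15; 0.00120), endothelial markers in 10 of 11 (-0.16; 0.00120) and ependymal markers in 6 of 8 (-0.30; 0.00389). With an estimated correlation these were adjusted p = 0.936 for ribosomal proteins, chaperones, dentate and oligodendrocyte markers, 0.522 for blood, 0.778 for choroid plexus and endothelial markers and 0.846 for ependymal markers. Enpp2 was at 334 ± 116 against 638 ± 250 CPM (-0.94) and Hba-a2 at 96.3 ± 66.5 against 41.5 ± 8.98 CPM (1.22). Interferon-stimulated genes had a median of 0.17 (0.191) and reactive glia genes of 0.42 (0.840), with C3 at -0.99 and Spp1, which encodes osteopontin, at 2.56 (261 ± 372 against 44.3 ± 13.7 CPM). The interferon list was called higher without the 4 libraries far out on component 1 (camera adjusted p = 0.000267) and without the 3 of lowest choroid plexus score (camera adjusted p = 0.0462). Single libraries turned both medians. The interferon median was -0.07 without Rnf20-labelled replicate 4 and 0.05, 0.10 and 0.34 without naive replicates 1, 2 and 9. The reactive glia median was -0.07 without Rnf20-labelled replicate 18, where the list was called lower (camera adjusted p = 0.00131). Without replicates 4 and 14 that median was 0.62 and 0.65 and the list was called higher. The interferon list was called higher without naive replicate 9 or 11 or Rnf20-labelled replicate 14 (camera adjusted p down to 0.00377), and its median was 0.28 without the last. The camera direction of reactive glia turned to lower in 7 of the 10 fits with 1 library left out and that of interferon in 2. Adjusted over the list alone 0 genes of these 10 lists passed, and 5 blood genes did without Rnf20-labelled replicate 14.

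The small calls rested on single libraries. Without Rnf20-labelled replicate 14 those for chaperones (median -0.02), dentate (0.13), oligodendrocyte (-0.08) and ependymal markers were lost, and the ribosomal median was 0.18. Without replicate 18 those for ribosomal proteins (-0.01; adjusted p = 0.960) and endothelial markers (-0.06) were lost, and the ependymal median was -0.49. Without replicate 20 that for ependymal markers (-0.12) was lost, the endothelial median was -0.10 and the dentate median 0.31, and without replicate 4 the dentate call was lost and the oligodendrocyte median was -0.23. The dentate call was also lost without replicate 8 or naive replicate 9, 11 or 12 (adjusted p up to 0.459). Without naive replicate 11 those for chaperones (0.02), oligodendrocyte and endothelial markers were lost, without naive replicate 2 that for chaperones (0.03), and without naive replicate 12 the chaperone median was 0.10. The lost calls had adjusted p up to 0.498 for chaperones, 0.258 for oligodendrocyte, 0.0883 for endothelial and 0.266 for ependymal markers. Medians without the 4 libraries far out on component 1 were -0.02 for chaperones, 0.05 for ribosomal proteins and -0.03 for endothelial markers, and the calls for chaperones, dentate, oligodendrocyte and endothelial markers were lost (camera adjusted p up to 0.643). Without the 3 of lowest choroid plexus score that for ependymal markers was lost (-0.14; camera adjusted p = 0.180). Limma-voom with quality weights gave 0.05 for ribosomal proteins and -0.07 for endothelial markers, and the dentate call was lost with the microglia covariate (camera adjusted p = 0.0753).

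Lists not called in this comparison with all libraries were called in some fits as well. Without Rnf20-labelled replicate 18, glutamate, presynaptic, channel, cAMP, long adhesion and clock genes were called higher and microglia and meningeal markers lower (adjusted p up to 0.00661). Without replicate 14, GABA genes, CA3 and pan-neuronal markers were called lower, without replicate 20 presynaptic genes and neocortex markers, and without replicate 8 pericyte and meningeal markers (adjusted p up to 0.0494). Without naive replicate 9, clock genes were called higher and CA1, microglia and pericyte markers lower. Without naive replicate 11, CA3 markers were called lower. Without naive replicate 12, other chromatin genes were called higher and pericyte markers lower (adjusted p up to 0.0478).

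Over all 14880 genes, edgeR called 0 for trained libraries labelled Rnf20 siRNA against naive libraries (smallest adjusted p = 1.00), with 342 at an unadjusted p under 0.05 (180 higher, 162 lower) where chance gives 744. Limma-voom called 0, DESeq2 called 1, Per1 (adjusted p = 0.00922), and edgeR called the same gene without naive replicate 9 (adjusted p = 0.0184). Camera called 11 lists (7 higher, 4 lower), 18 without Rnf20-labelled replicate 18 and 0 with an estimated correlation, and fry called 0. The median, mean and camera direction differed in sign for 4 lists, none of them called: channels, astrocytes, microglia and pericytes. No naive libraries labelled Rnf20 siRNA exist among the samples, so training and siRNA cannot be separated in this contrast.

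The F test among the 3 groups asks whether any gene differs at all. EdgeR called 0 of 14880 genes (smallest adjusted p = 0.743), with 959 at an unadjusted p under 0.05. DESeq2 called 10 and limma-voom 0, and edgeR called 1 without naive replicate 9.

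Genes that were higher with training tended to be lower in libraries labelled Rnf20 siRNA than in scrambled trained libraries. Shared libraries give at least part of this relation with no change in any gene. Across the 14880 genes, which are not independent replicates, the fold changes of the 2 contrasts had Pearson's r = -0.726 and Spearman's rho = -0.702, with a covariance of -0.0692. Both contrasts use the 5 scrambled trained libraries with opposite sign, and 20 simulated data sets without any change gave a mean r of -0.495 (SD 0.0158) and a covariance of -0.0302, so the covariance differed from the simulated one by -0.0390. The simulation drew each gene independently, so its SD leaves out the correlation between genes and is too narrow to judge that difference. With separate scrambled trained libraries for each contrast, r averaged -0.288 over 20 splits of the 5 libraries (-0.528 to 0.05) with a mean covariance of -0.0330. Of 100 regroupings of the 15 libraries, the real one included, 10 gave an r as low, with a median of -0.471 and a range of -0.868 to 0.104. The fold changes of the training contrast and of trained libraries labelled Rnf20 siRNA against naive, which share the naive libraries, had r = 0.683 and a covariance of 0.0613, against 0.499 and 0.0305 simulated, and 17 of 100 regroupings gave an r as high. EdgeR called 0 genes in either contrast, so 0 were shared. By DESeq2 0 genes were shared between training and the trained groups' contrast, and 1 between training and trained Rnf20-labelled against naive libraries.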

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

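The tests of microglia content, of 1 library carrying the proteasome difference and of the 3 explanations for Rnf20, as well as the fits without chosen libraries or with the microglia covariate and the permutation of list scores, were chosen only after the results were seen.

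Of 135 groups of 5 values (list scores and library measures), 8 held a library whose gap to its nearest neighbour was over 0.71 of the group's range, where chance at 5% gives 6.8. Scrambled trained replicate 16 was lowest for H3K4 and H3K79 enzymes (5.28, next 5.51) and for other chromatin genes (5.04, next 5.17). Naive replicate 11 was lowest for cholesterol synthesis (5.80, next 5.93) and CA3 markers (5.88, next 6.14), and naive replicate 9 highest for meningeal markers (3.30, next 3.15). Scrambled trained replicate 10 was highest for meningeal (3.66, next 2.75), thalamus (4.53, next 3.71) and striatum markers (5.85, next 3.22).

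Interferon-stimulated genes were higher in scrambled trained libraries, with a score difference of 0.95. More microglia in the tissue piece may account for part of it: the trained minus naive difference of the interferon score less the microglia score was 0.563 (SE 0.409), within 2 SE of both 0 and the full difference, so that test leaves the explanation open. With the microglia score as a covariate the median log2 fold change was 0.77 in place of 1.07, and the score difference 0.38 (SE 0.50), which leaves it open too (the lists share 0 genes). Whether a few strongly reacting animals account for it cannot be told apart from an effect of training: without the 4 libraries far out on component 1 the median was 0.30, but those libraries include scrambled trained replicate 15, with the highest interferon score of its group (5.18), so a fall was built into that test. Training itself stays among the open explanations, untested apart from these.

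Proteasome genes were higher in scrambled trained libraries than in both other groups. With the microglia score as a covariate the median log2 fold change was 0.14 against 0.13 without it. The values argue against a tissue reaction that relates alike to that score in all groups as the whole cause. The fit gives the score 1 slope for all groups, so it cannot decide about a relation found only in scrambled trained libraries. The proteasome score was 6.56 in scrambled trained replicate 15 (microglia score 6.59) and 6.42 in replicate 5 (5.60). Among Rnf20-labelled libraries it was 6.34 in replicate 18 (6.54) and 6.44 in replicate 14 (5.10). The tables argue against 1 library carrying the difference: with each of the 10 libraries left out in turn, the score difference was at least 0.098, against 0.121 (SE 0.0371) with all. Training and the siRNA label may each play a part, but the group of libraries labelled Rnf20 siRNA showed no lower Rnf20, gene length and GC content were not tested, and the preset-correlation calls come from a test whose number of called lists other divisions of the samples matched.

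Rnf20 was not lower in libraries labelled Rnf20 siRNA. A swap of trained libraries between the siRNA labels would give a scrambled trained library low Rnf20 only if the siRNA lowered the mRNA measured here. The lowest scrambled trained library held 87.1% of the naive mean. That value argues only against a swap of libraries with clearly lowered Rnf20 mRNA and cannot decide about other swaps. Too few reads or too wide a spread is argued against by the interval of the change, whose lower end was -14.2%. Knockdown in only part of the dissected tissue could hide a loss and cannot be told apart from no knockdown: the CA1 marker scores of the trained groups differed by -0.10 (SE 0.36), and no value separates injected cells from others. Recovery of the mRNA by the time of dissection was not tested.

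Other divisions of the same libraries gave as many called lists, so chance cannot be excluded for the list counts. For edgeR's gene counts of 0 the comparison decides nothing, because each of the 100 divisions gives at least 0; the highest other count was 1 for training, 3907 for the trained groups, 0 for trained Rnf20-labelled against naive libraries and 478 among the 3 groups. For lists called by camera with the preset correlation, 25 of 100 divisions gave as many as the 20 for training (highest other 25), 44 as many as the 19 for the trained groups (highest other 26) and 76 as many as the 11 for trained Rnf20-labelled against naive libraries (highest other 27). The division with 3907 genes put 2 scrambled and 3 Rnf20-labelled libraries on one side and parted the 10 trained libraries by component 1 (at most -9.33 on one side and at least 9.19 on the other) and by reactive glia score (at most 4.49 and at least 5.06), which points to a structure of the samples. At an unadjusted p under 0.05, 14 of 100 divisions gave as many genes as the 1484 for training (highest other 3466), 35 as many as the 835 for the trained groups (5932), 59 as many as the 342 (2153) and 19 as many as the 959 among the 3 groups (3170).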

How the results depend on the processing

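The fits without chosen libraries or with the microglia covariate and the permutation of list scores were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. For the counts of genes called by edgeR, all 0, DESeq2 gave 53 for training, 1 for the trained groups, 1 for trained Rnf20-labelled against naive libraries and 10 among the 3 groups, with 1 gene shared between training and trained Rnf20-labelled against naive libraries; in simulation DESeq2 had more false calls than edgeR, but the cause was not tested. Adding 1 surrogate variable gave 1 for training. Leaving out each library gave 0 for training and the trained groups, and 0 to 1 for trained Rnf20-labelled against naive libraries and among the 3 groups, with 1 without naive replicate 9. The other scalings, filters, limma-voom fits and the fit of only the 2 groups gave 0.

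The list counts of 20, 19 and 11 became 0 with an estimated correlation, with fry and with permutation of scores; the last can pass no list unless at least 7 pass together, so its 0 is nearly fixed by the design, while all these tests allow for correlation within a list, and the estimated correlation had a median of 0.431. The count for the trained groups was 11 with the microglia covariate. Leaving out Rnf20-labelled replicate 18 raised the count for trained Rnf20-labelled against naive libraries from 11 to 18. The cause was not tested for either. Ribosomal proteins between the trained groups turned from lower to higher with 1 surrogate variable (adjusted p = 0.00642) and with the microglia covariate (adjusted p = 0.00847); the cause was not tested. Of 117 list tests, 50 lost their call with an estimated correlation and 50 with fry; without the 4 libraries far out on component 1, 20 gained and 21 lost it; 0 changed with median-ratio or upper-quartile scaling.

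The correlation of training and trained-group fold changes, -0.726, was -0.508 without a filter, -0.750 with the stricter filter, -0.688 with 1 surrogate variable, -0.699 without the 4 libraries, -0.793 without the 3 libraries low in choroid plexus, -0.596 with the microglia covariate, -0.288 with separate scrambled trained libraries, and -0.781 to -0.593 with each library left out; it was negative in each fit, but with separate libraries the 20 splits ran from -0.528 to 0.05, and the cause of the moves was not tested. The Rnf20 contrast stayed on its side of the threshold in every alternative run. Of 6017 alternatives of 274 named gene values, 16 passed the threshold and 54 had the other sign. The count of reversed calls, 0, decides nothing, because the main fit called 0 genes and left no call to reverse. Genes of low count were recovered least: over the 3 simulations edgeR called 19.8% of 96 genes changed 1.5-fold with a mean count below the median of the tested genes and 65.7% of 105 at or above it; depth was not separated from a larger spread between libraries.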

Other observations

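The mitotic gene test was planned after mitotic genes were seen among those of smallest p for training and before its own result was known; the fit without 4 libraries was chosen after the data were seen.

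Genes of dividing cells, a group outside the fixed lists, were higher in scrambled trained than in naive libraries. A list of 24 mitotic genes, without those called by DESeq2, was written for the test. All 24 were above 0 for training, with a median log2 fold change of 1.30, and 21 rose adjusted over the list alone by edgeR; blood transcripts were higher in scrambled trained libraries too, with a median of 2.08. The score was 3.25 ± 0.74 against 2.17 ± 0.27 (n = 5 each; difference 1.08, exact permutation p = 0.0317). In libraries labelled Rnf20 siRNA 24 of 24 were lower than in scrambled trained libraries (median -0.97; exact permutation p = 0.0873; 0 adjusted over the list alone), and against naive libraries 24 of 24 were above 0 (median 0.30; score difference 0.11, exact permutation p = 0.794; 0 adjusted over the list alone).

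A change of dividing-cell transcripts with training is a hypothesis that this test, at p = 0.0317, leaves standing by exact permutation, but genes of the same process had been seen to differ in the same libraries, so it is not independent evidence. With each library left out the difference was 0.886 to 1.38, and without the 4 libraries far out on component 1 it was 0.720 (exact permutation p = 0.0893). The score was 4.05 and 3.55 in scrambled trained replicates 10 and 15 and 3.50 in Rnf20-labelled replicate 18, which lie high on component 1, but also 3.52 in scrambled trained replicate 6, at -9.33 on component 1 and with a reactive glia score of 4.49, inside the naive range. Blood transcripts were high in the same libraries: the blood score was 6.69 in scrambled trained replicate 6, 5.63 in 10, 5.54 in 15 and 5.16 in Rnf20-labelled replicate 18, against 3.13 to 3.62 in naive libraries, and scrambled trained replicate 5 was low in both, with a mitotic score of 2.09 and a blood score of 3.55. Rnf20-labelled replicate 8, in contrast, had a blood score of 5.25 and a mitotic score of 2.63, near the naive range of 1.75 to 2.45. Which cells hold the mitotic transcripts, and whether blood in the tissue accounts for them, was not tested.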
